A study of Rattus norvegicus and Homo sapiens with 48 samples.

How the data were processed

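Total RNA was isolated with TRIzol and made into libraries with the Fast RNA-seq Lib Prep Kit V2, per the labels' protocols, which do not state the strandedness of the kit. The 48 libraries cover 2 cell lines, 8 groups per line and 3 replicates per group, and the groups were taken from the treatment given in the labels. PC12 carries batch label 1 and SH-SY5Y batch label 2, so line, species and batch are the same split. Cells were grown in DMEM with 10% fetal bovine serum, per the labels' protocols.

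The deposited values are raw counts per gene, 1 table per line, with 48 columns used. CASAVA 1.8, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 are named in the submitters' processing notes without a role for each. The same notes name the build GRCh38 for all samples; a rat build is not given in the sources used here, so rat coordinates are those of the table, on an unnamed build. The authors also deposited FPKM tables. Their values equal the count divided by gene length and by a library total that matches a median-ratio size factor (ratio 1 in every library), and they served only to check the counts. Their 16 columns of group means were not used. The PC12 table has 31165 rows and that of SH-SY5Y 61845, with gene name, position, length and biotype. Unnamed gene models assembled by the authors (605 and 312 rows) hold 0.423% and 0.237% of the counts and stayed in the fit. No row of the tables lacked a gene.

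Depth ranged from 33955297 to 46553917 counts per library in PC12 and from 14769484 to 18112895 in SH-SY5Y. Genes with few counts were removed with filterByExpr (minimum count 10), which left 15547 genes in PC12, 13666 of them protein-coding, and 19412 in SH-SY5Y, 13778 of them protein-coding. All counts were normalised by TMM, and CPM values are TMM-scaled except where CPM of total counts is stated (mitochondrial RNA and the bar plots of single genes). Mitochondrial genes took 1.567% to 3.822% of the counts in PC12 and 4.801% to 5.838% in SH-SY5Y.

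Each line was fitted alone, with 24 libraries, 1 mean per group and 16 residual degrees of freedom, using edgeR 4.0.16 (estimateDisp, robust glmQLFit, glmQLFTest) in R 4.3.3. The common dispersion was 0.00909 in PC12 and 0.00487 in SH-SY5Y. P-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The 14 comparisons per line were H2O2 against DMEM, each of the 6 treated groups and all of them together against H2O2, high against low dose of each of 3 compounds, and each compound against the other compounds. Treated groups were also set against DMEM. The difference of responses between the lines was tested as an interaction in 1 edgeR fit of all libraries over 13330 genes, of 15955 with a symbol found once in both tables. All pooled contrasts weigh groups equally.

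27 gene lists of stress, metabolic, cell-cycle, neuronal and cell-type marker genes were fixed before the data were examined, as were the comparisons, tests and alternatives except where the closing section says otherwise. Rat symbols were matched in capitals. A list was tested where at least 5 members were measured, with camera (limma 3.58.1, preset inter-gene correlation 0.01) and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Members called were counted after adjustment over all genes and over the list alone. Genes named in the text follow a rule of the same date: protein-coding, called, at a mean of 10 CPM or more on one side and with no overlap of the libraries compared, those of largest log2 fold change (8 up and 8 down for H2O2, 3 and 3 between doses, 5 and 5 in the other comparisons), with up to 4 list members of smallest p per list. From these, the text gives a part. With 3 libraries against 3, chance gives no overlap for 10% of genes. The results of some single genes that meet the rule are not reported here, and the closing section leaves them out of its counts of gene values.

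The edgeR steps were tested on simulated counts drawn from the means and dispersions of the real libraries with 200 genes changed. For extract high against H2O2 in PC12 (15114 genes), 34%, 80%, 92% and 98% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 5.03% of calls were false; in SH-SY5Y (18489 genes) the shares were 46%, 78%, 92% and 98%, with 5.88% false. For the interaction (13208 genes) they were 12%, 60%, 98% and 100%, with 6.25% false. Under DESeq2 10.7% and 7.69% of calls were false in the PC12 and SH-SY5Y simulations.

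Alternatives fixed in advance were the DESeq2 1.42.0 Wald test, median-ratio size factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were an adjustment for gene length in both lines, one for gene length and GC content in SH-SY5Y, and leaving out the PC12 libraries mannitol low replicate 1 and ergosterol high replicate 3 together. GC content was taken from the longest transcript of each gene in GENCODE v29 and was available for 96% of the SH-SY5Y genes tested; no rat sequence was available, so GC was not adjusted in PC12. Length and GC trends were removed per library as splines with 5 degrees of freedom and entered as offsets. Returns toward DMEM and overlaps of treated groups were set beside 20 simulated draws of unchanged groups. In these all libraries were redrawn from group means and gene dispersions, with the treated means set to the H2O2 mean. A bias shared by the real H2O2 libraries is thus not part of the simulated spread. The position of a library between DMEM and H2O2 was the projection of its log2(CPM + 1) profile on the difference of the 2 group means, over the genes that H2O2 changed more than 2-fold. Splits of the samples into other groups were counted by refitting the libraries compared. Tables were handled with data.table (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9.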

Results

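RNA was sequenced from 2 cell lines exposed to hydrogen peroxide (H2O2) and then to products of the caterpillar fungus Cordyceps sinensis. PC12 is a line derived from a rat tumour of the adrenal medulla, and SH-SY5Y is a human neuroblastoma line; both serve as culture models of neurons. Each line had 8 groups of 3 biological replicates, 48 libraries in all. One group was kept in DMEM for 24 h, and one was exposed to H2O2 for 24 h at a concentration given as 400 mM in the labels, a unit that could not be checked here. The other 6 groups received H2O2 for 24 h and then, for a further 24 h, the fungal extract mixture at 25 or 50 µg/ml, D-mannitol, a sugar alcohol, at 5 or 20 µM, or ergosterol, the main sterol of fungal membranes, at 1 or 3 µM. The smaller of each pair of doses is called low here and the larger high. The title of the series names neuroprotective effects of these products as its subject. By the labelled times, both the DMEM and the H2O2 group were collected 24 h before the treated groups. Each comparison of a treated group with either of them thus also spans that time. Comparisons among treated groups do not. Total counts per library ranged from 33955297 to 46553917 in PC12 and from 14769484 to 18112895 in SH-SY5Y, and 15547 and 19412 genes were tested. A gene is said to have risen or fallen, or to be called, where edgeR's quasi-likelihood test gave an adjusted p under 0.05. The edgeR p-values of single genes rest on the spread between replicates within groups, estimated over all groups of a fit. Those of camera set the members of a list against other genes, with a preset inter-gene correlation.

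The first question was what H2O2 did to each line. In PC12, Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1 (ENSRNOG00000014117, chromosome 19, 13467244 to 13474079), rose from 47.43 ± 3.34 CPM in DMEM to 1792 ± 27.6 CPM after H2O2 (SD, n = 3 each), a log2 fold change of 5.24 ± 0.172 (SE; adjusted p = 6.9e-16). Zfand2a, a stress-induced partner of the proteasome, rose from 18.7 ± 1.11 to 903.3 ± 35.8 CPM. Other steep rises were the chemokine gene Cxcl1 by 5.62 ± 0.12 (6.099 ± 0.924 to 302.2 ± 13 CPM), the growth factor gene Csf2 by 6.92 ± 0.391 and Serpinb2, an inhibitor of plasminogen activators, by 6.46 ± 0.447. Among the genes that fell most were the collagen gene Col12a1, from 1014 ± 39.7 to 141.1 ± 11.4 CPM (log2 fold change −2.85 ± 0.155), Cenpe, a kinetochore motor (−2.55 ± 0.208), Tril, an accessory protein of Toll-like receptors (−3.19 ± 0.195), and the mitochondrial gene Mt-nd6 (−2.56 ± 0.282). ENSRNOG00000045654 and ENSRNOG00000050647, with the largest rises of 8.04 ± 0.749 and 7.84 ± 0.496, are overlapping models on opposite strands of chromosome 20 (3856006 to 3873227 and 3856006 to 3873240). Whether counting used strand is not stated, so their reads cannot be told apart. Of the 15547 genes, 4739 rose and 4545 fell, and 2813 of these 9284 changed by more than 2-fold. Across genes the fold changes ran against gene length (Spearman −0.316, genes not being independent replicates): longer genes were lower after H2O2.

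The gene lists, fixed before the data were examined, showed which programs moved in PC12. Of 19 p53 target genes, 16 rose and 1 fell (median log2 fold change 2.22, camera adjusted p = 2.71e-35), led by the cell-cycle inhibitor Cdkn1a (2.90 ± 0.06), the p53 ubiquitin ligase Mdm2 (3.50 ± 0.09) and the pro-apoptotic Bbc3 (3.29 ± 0.08). Of 16 targets of NRF2, the regulator of antioxidant genes, 12 rose and 1 fell (adjusted p = 7.43e-15), with Nqo1 at 2.43 ± 0.07, Txnrd1 at 1.90 ± 0.07 and Osgin1 at 4.69 ± 0.18. Of 12 heat shock genes 11 rose and none fell (median 1.93, adjusted p = 2.53e-09), among them the chaperone gene Hspa8 (1.62 ± 0.09) and its cochaperone Bag3 (2.89 ± 0.17); adjusted p = 0.0563 with an estimated correlation. Rises also led in the NF-kB and inflammatory genes (10 up and 1 down of 11, adjusted p = 2.89e-18; Tnfaip3 2.89 ± 0.09) and the immediate early genes (11 up and 1 down of 12, adjusted p = 1.2e-09; Ier3 2.60 ± 0.08 and Myc 3.65 ± 0.18). They also led in the iron handling genes (7 up and 2 down of 10, adjusted p = 3.48e-07; Tfrc, the transferrin receptor, 2.54 ± 0.08) and the apoptosis genes (11 up and 3 down of 17, adjusted p = 0.000658). All 14 cytosolic ribosomal protein genes rose (median 0.702, adjusted p = 3.41e-05), as Rps19 did by 0.79 ± 0.06; adjusted p = 0.106 with an estimated correlation. Every one of these counts was the same when adjusted over the list alone. No PC12 list, rising or falling, was tested with the trend of fold changes with gene length removed.

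Other lists fell in PC12. All 16 mitosis genes fell (median −1.26, adjusted p = 2.02e-15), including the cyclin gene Ccnb1 (−1.13 ± 0.06) and the spindle motor Kif11 (−1.47 ± 0.08). Of 15 DNA replication genes 13 fell and 1 rose (median −0.62, adjusted p = 6.42e-05), with the helicase subunits Mcm2 at −1.14 ± 0.08 and Mcm3 at −0.95; adjusted p = 0.106 with an estimated correlation. Cholesterol synthesis genes were lower in 11 and higher in 4 of 20 (12 and 5 adjusted over the list alone; camera adjusted p = 0.00268), and their regulator Srebf2 fell by 1.30 ± 0.06; adjusted p = 0.0563 with an estimated correlation. All 13 mitochondrially encoded genes fell (median −1.66, camera adjusted p = 0.00154; adjusted p = 0.432 with an estimated correlation). Messenger RNA of this genome made up 37410 ± 435 CPM in DMEM and 11700 ± 525 CPM after H2O2 (SD, n = 3 each). Mitochondrial ribosomal RNA was 61.9-fold higher after H2O2, at 19040 ± 664 against 307.8 ± 12.1 CPM. In SH-SY5Y it stood at 9854 ± 480 CPM already in DMEM. Mesenchymal and fibroblast marker genes fell in 11 and rose in 1 of 13 (adjusted p = 0.000795; adjusted p = 0.0837 with an estimated correlation). Schwann and glial marker genes fell in 5 and rose in 1 of 9 (adjusted p = 0.0211; adjusted p = 0.097 with an estimated correlation), with Gfap at −2.04 and S100b at −0.86. These counts, the mitosis and DNA replication counts included, were otherwise the same adjusted over the list alone. Markers of the chromaffin cell were scarce in these cells before any exposure: 16 catecholamine and secretory granule genes had a median of 0.0375 CPM in DMEM, and Th, the first enzyme of dopamine synthesis, stood at 0.00947 CPM, while Scg2 reached 209 ± 7.73 CPM.

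**Figure D1:**
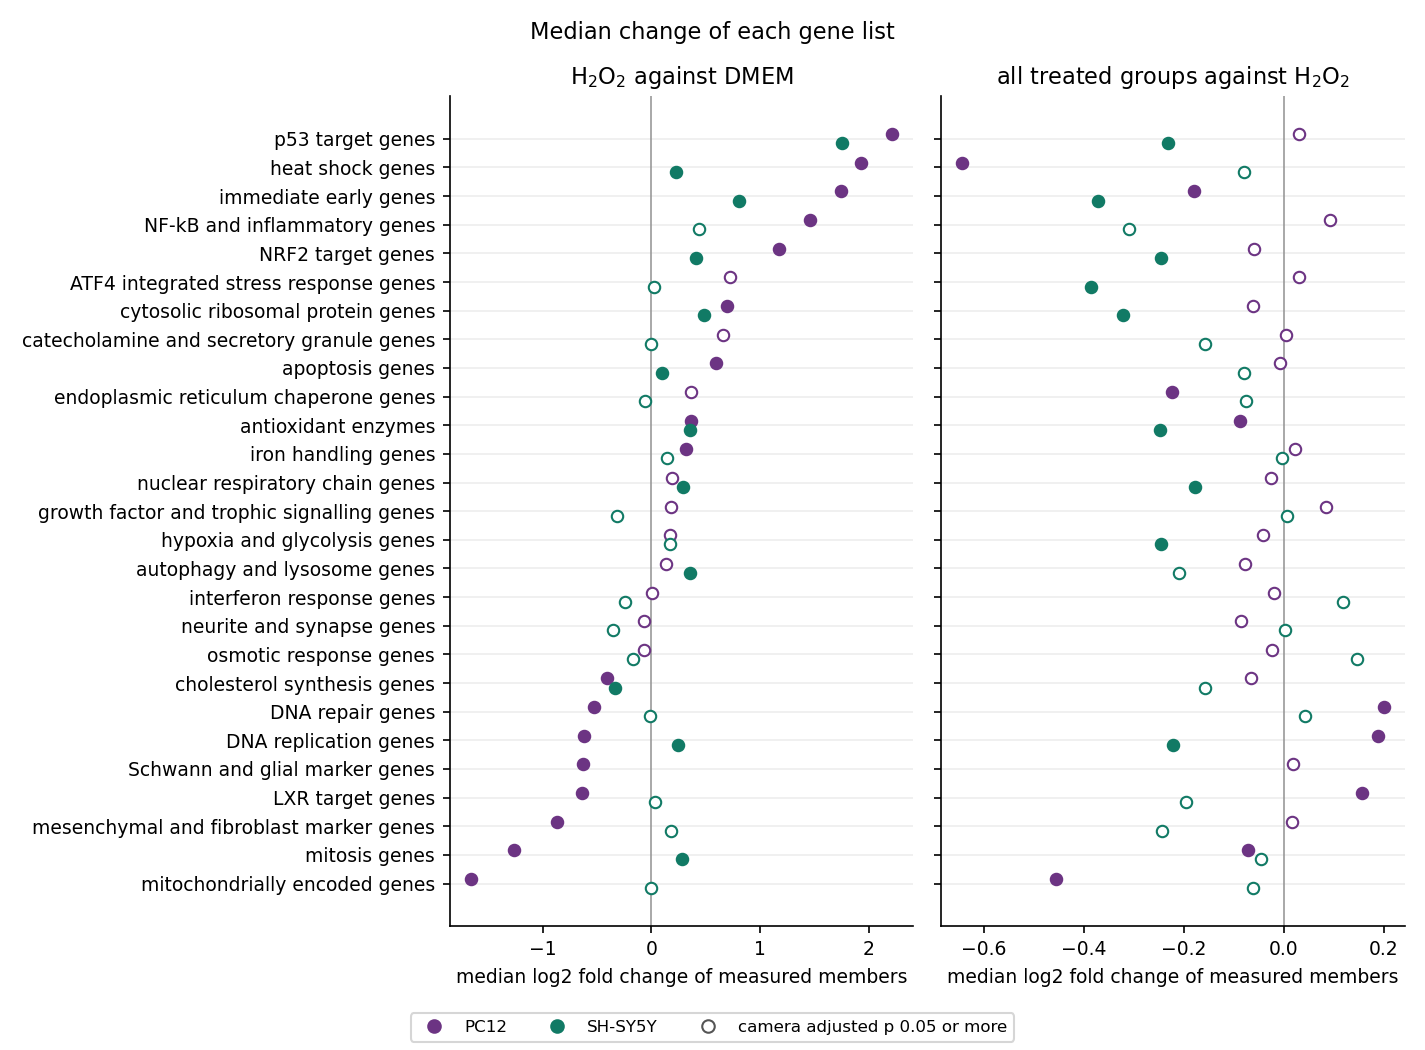
Median log2 fold change of the measured members of each gene list, H2O2 against DMEM on the left and all treated groups against H2O2 on the right, PC12 in purple and SH-SY5Y in green; open circles are lists with a camera adjusted p of 0.05 or more. The p53 targets lie at 2.22 in PC12 and 1.76 in SH-SY5Y after H2O2, and the PC12 heat shock genes at 1.93 after H2O2 and −0.644 in the treated groups.

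In SH-SY5Y the same exposure raised CDKN1A (ENSG00000124762_14; GRCh38 chromosome 6, 36676460 to 36687337) from 20.32 ± 4.84 to 834.7 ± 42.2 CPM (SD, n = 3 each), a log2 fold change of 5.36 ± 0.15 (SE; adjusted p = 2.83e-15). GDF15, a secreted stress factor (chromosome 19, 18374731 to 18389176), rose by 6.71 ± 0.246 to 341.9 ± 27.7 CPM, and the inducible chaperone gene HSPA6 by 8.84 ± 0.704 from almost no reads. NOTCH1, a receptor of cell fate signalling, rose by 4.41 ± 0.17, ACTA2, smooth muscle actin, by 5.59 ± 0.169, and FOSL1, an AP-1 subunit, by 4.49 ± 0.287. Steep falls included GRIA2, a glutamate receptor subunit, from 45.54 ± 2.85 to 10.62 ± 2.4 CPM (−2.11 ± 0.147), and RAB27B, a GTPase of vesicle exocytosis, from 26.89 ± 3.72 to 5.304 ± 0.752 CPM (−2.35 ± 0.132). The kinase gene MAP2K6 fell by 1.97 and ZMAT1 by 1.93. The test called 9594 of 19412 genes, 4535 higher and 5059 lower, 1630 of them by more than 2-fold. Fold changes rose with GC content across genes (Spearman 0.425) and fell with gene length (−0.365); with both trends removed 9010 genes were called, 6562 of the 9594 in the same direction and 235 in the opposite one.

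All 21 p53 target genes rose in SH-SY5Y (median 1.76, camera adjusted p = 4.64e-95), with BTG2 at 2.84 ± 0.08, the death receptor TNFRSF10B at 1.90 ± 0.06 and SESN1 at 1.52 ± 0.06. All 21 also rose after removal of the GC and length trends. The 15 ribosomal protein genes rose together (median 0.484, adjusted p = 3.14e-11), RPS19 by 0.97 ± 0.06 and RPS9 by 0.69 ± 0.06; adjusted p = 0.0844 with an estimated correlation. Heat shock genes rose in 8 and fell in 1 of 13 (median 0.229, adjusted p = 2.26e-05), with DNAJB1 at 1.05 ± 0.06. NRF2 targets rose in 12 and fell in 3 of 17 (adjusted p = 0.000594), NQO1 by 1.77 ± 0.10; adjusted p = 0.0599 with an estimated correlation. Cholesterol synthesis genes fell in 13 and rose in 1 of 21 (median −0.335, adjusted p = 0.00176). Mitosis genes rose in 11 and fell in 4 of 16 (adjusted p = 0.0106; adjusted p = 0.167 with an estimated correlation). Immediate early genes rose in 11 and fell in 1 of 12 (adjusted p = 0.00118; adjusted p = 0.161 with an estimated correlation), the exception being MYC (−1.04 ± 0.06). The counts named here were the same adjusted over the list alone. With the GC and length trends removed the median of the NRF2 targets went from 0.413 to 0.212, with 10 up and 3 down. Among single genes of other lists, BAX, a pro-apoptotic effector, rose by 2.14 ± 0.08, and MAP2, a dendritic microtubule protein, fell by 1.18. Mitochondrial messenger RNA differed 1.01-fold between H2O2 and DMEM in this line and mitochondrial ribosomal RNA 1.41-fold.

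**Figure D2:**
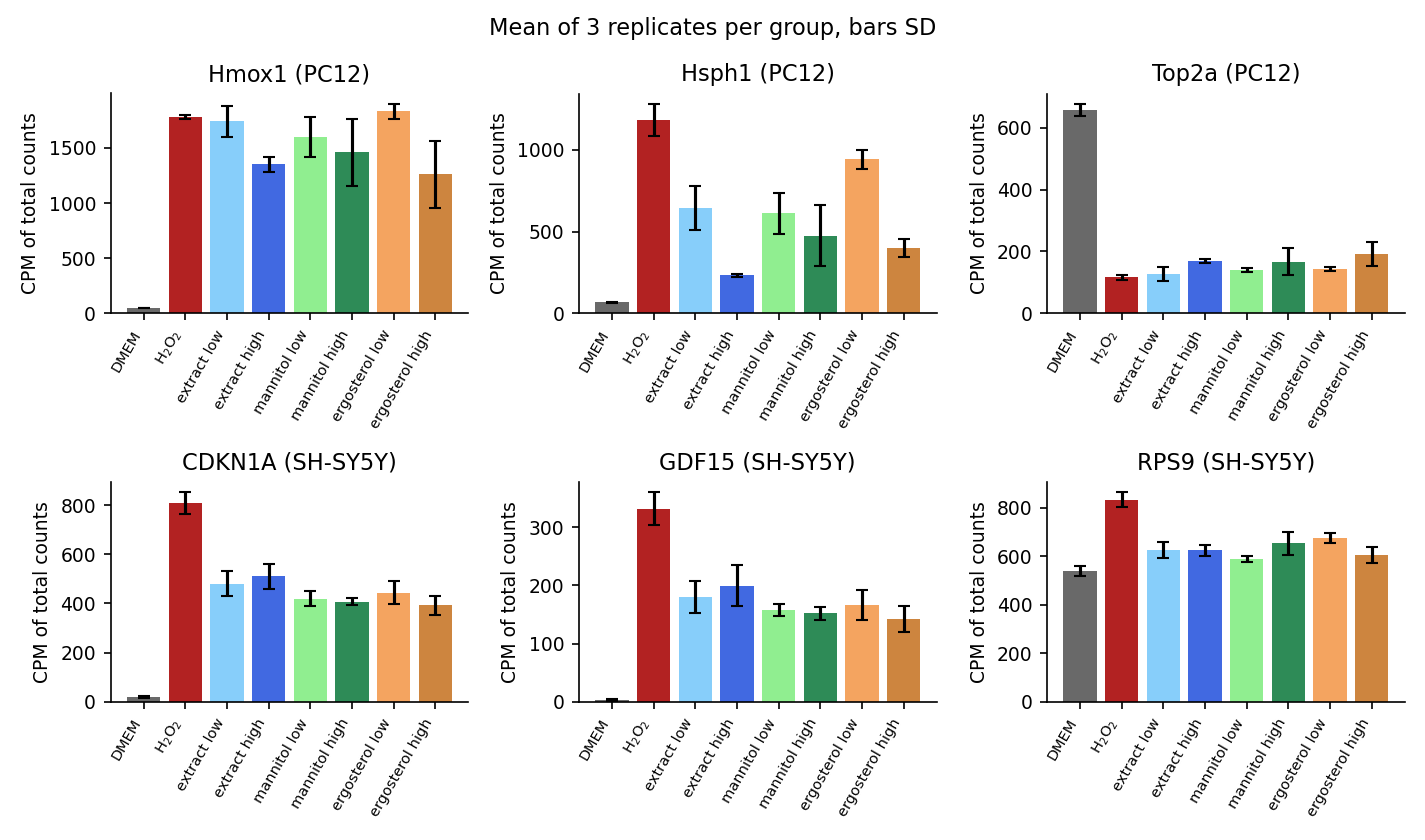
CPM of total counts (no TMM scaling) of 3 genes in PC12 and 3 in SH-SY5Y, one bar per group with the mean and SD of 3 replicates. Hsph1 stands at 1180 CPM after H2O2 and 233 CPM with extract high, and CDKN1A at 807 CPM after H2O2 and between 392 and 510 CPM in the treated groups.

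The H2O2 effect was compared between the lines by an interaction over the 13330 genes tested that share a symbol. NRF2 targets rose more in PC12 than in SH-SY5Y: 11 of 16 had a smaller effect in SH-SY5Y and 0 a larger one by edgeR (11 and 0 adjusted over the list alone; medians 1.2 and 0.39, adjusted p = 2.16e-05). Heat shock genes likewise rose more in PC12 in 10 of 12 and less in 1 (the same adjusted over the list alone; medians 1.95 and 0.12, adjusted p = 1.26e-06; adjusted p = 0.107 with an estimated correlation). All 16 mitosis genes and 13 of 15 DNA replication genes had a less negative effect in SH-SY5Y (16 and 13 adjusted over the list alone, with 1 replication gene the other way; medians −1.24 and 0.265, and −0.597 and 0.224; adjusted p = 1.48e-21 and 3.21e-08). Mesenchymal and fibroblast markers had a less negative effect in SH-SY5Y in 10 of 16 (10 adjusted over the list alone; adjusted p = 0.000353). All 13 mitochondrially encoded genes did too (13 adjusted over the list alone; adjusted p = 5.53e-05; adjusted p = 0.426 with an estimated correlation). The largest differences of single genes were in NOTCH1 (5.17 ± 0.233; −0.78 in PC12 and 4.39 in SH-SY5Y), FDXR, a mitochondrial reductase and p53 target (3.16 ± 0.15), ZFAND2A (−5.16 ± 0.347; 5.62 and 0.46), MYC (−4.73 ± 0.188; 3.67 and −1.06) and TFRC (−3.06 ± 0.102; 2.56 and −0.50). The effects differed for 6416 genes, larger or less negative in SH-SY5Y for 3052 and the reverse for 3364. Of 4293 genes called in both lines, 2813 moved in the same direction, against 1965 expected of independent lists, and 1480 in opposite directions, against 1964. The lines were sequenced under different batch labels, so line and batch cannot be told apart. A matched symbol is not a proof of orthology. No interaction was fitted with the GC and length trends removed, so their part in these differences was not tested.

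The second question was what followed H2O2 in the cells given a compound. Over the 18 treated PC12 libraries together, Hsph1, a chaperone of the HSP110 family (ENSRNOG00000000902, chromosome 12, 5390922 to 5410224), was at 551.8 ± 248 CPM against 1188 ± 92.2 CPM in the H2O2 group (SD, n = 18 and 3), a fall of −1.24 ± 0.164. Serpinb2 fell by 1.77 ± 0.197, the transcription factor gene Klf2 by 1.49 ± 0.168 and the AP-1 gene Fosb by 1.28 ± 0.168. Egr2, a zinc-finger transcription factor, rose by 0.62 ± 0.0712, and Exo1, an exonuclease of DNA repair, by 0.46 ± 0.0724. Of 12 heat shock genes 11 fell (0 up and 11 down adjusted over the list alone; median −0.644, camera adjusted p = 3.8e-24), Hspa8 by 0.49 ± 0.06 and Hsp90aa1 by 0.56 ± 0.07. ER chaperones fell in 7 and rose in 1 of 15 (9 and 2 adjusted over the list alone; adjusted p = 1.35e-06), with Calr at −0.30; adjusted p = 0.0811 with an estimated correlation. DNA replication genes rose in 8 of 15 and none fell (11 adjusted over the list alone; median 0.189, adjusted p = 2.87e-08), with the licensing factor Cdt1 at 0.34 ± 0.06 and Mcm5 at 0.34 ± 0.06; adjusted p = 0.0638 with an estimated correlation. DNA repair genes rose in 6 of 15 and none fell (9 adjusted over the list alone; adjusted p = 3.13e-06; adjusted p = 0.0638 with an estimated correlation). The p53 targets as a list did not move relative to other genes (adjusted p = 0.891), nor did NRF2 targets (adjusted p = 0.356). The test called 1147 genes, 574 higher and 573 lower. Fold changes also rose with gene length (Spearman 0.264; between 0.0435 and 0.335 in the 6 groups), and the lists were not tested with that trend removed. The count rested on the H2O2 libraries and on 1 treated library: it was 347, 359 and 708 without H2O2 replicate 1, 2 and 3, and 2255 without mannitol low replicate 1.

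Each of the 6 PC12 treatments was then set against H2O2 by itself. These comparisons also span the further 24 h, so compound and time cannot be told apart in them. With extract high, Hsph1 stood at 233.6 ± 8.93 CPM (−2.35 ± 0.249; adjusted p = 1.81e-05), Serpinb2 at 2.16 ± 0.503 CPM (−3.50 ± 0.334) and Klf2 at 6.043 ± 1.57 CPM (−2.43 ± 0.262). In that group 11 of 12 heat shock genes fell (median −1.09, camera adjusted p = 1.45e-31; also 11 adjusted over the list alone). The inositol transporter gene Slc5a3 fell by 1.98 ± 0.17 and the activity-regulated gene Arc by 2.79 ± 0.33, while Mcm5 rose by 0.42 ± 0.07. With ergosterol high, 11 heat shock genes again fell (median −0.849, adjusted p = 3.43e-20; 11 adjusted over the list alone) and 12 of 15 DNA replication genes rose (median 0.323, adjusted p = 5.81e-13; 12 adjusted over the list alone). In the same group 9 of 15 DNA repair genes rose (11 adjusted over the list alone; adjusted p = 1.59e-09), with the replication initiator Mcm10 at 0.74 ± 0.0944 and Brca1 at 0.60. In the mannitol high group 8 heat shock genes were lower than after H2O2 (11 adjusted over the list alone, camera adjusted p = 4.66e-20). Klf2 was lower there by 1.71 ± 0.252. In the mannitol low group 6 heat shock genes were lower (8 adjusted over the list alone, camera adjusted p = 5.29e-09, adjusted p = 0.204 with an estimated correlation). Ccn2, a matricellular protein gene, was higher by 0.62 ± 0.124. Postn, an extracellular matrix protein gene, stood at 22.37 ± 2.49 CPM after H2O2 and at 9.048 ± 0.686 CPM with extract low (−1.30 ± 0.138). With ergosterol low the kinase gene Clk1 was lower by 0.60 ± 0.0785 and the NF-kB inhibitor gene Nfkbia by 0.58 ± 0.0852. Egr2 rose in 5 of these groups, by 0.41 ± 0.0889 with extract low, 0.80 with extract high, 0.71 with mannitol high, 0.53 with ergosterol low and 0.76 with ergosterol high. Mitochondrial ribosomal RNA stayed 33 to 53.5 times its DMEM level in the 6 groups and mitochondrial messenger RNA at 0.193 to 0.3 of it.

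**Figure D3:**
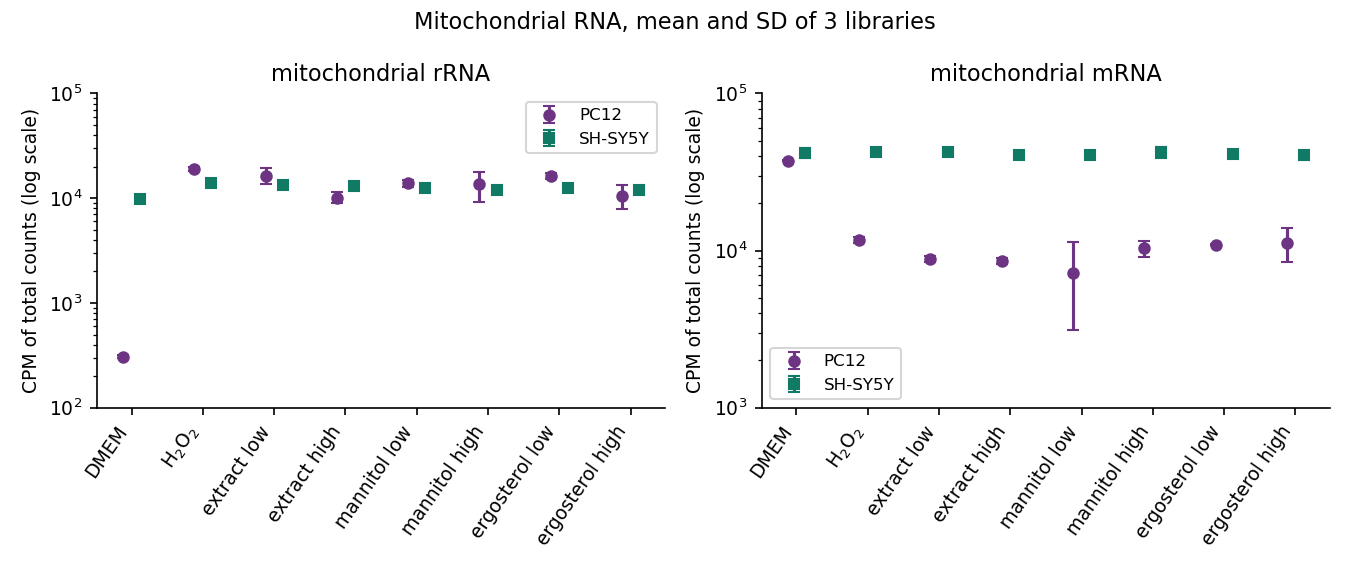
Mitochondrial ribosomal RNA (left) and messenger RNA (right) in CPM of total counts on a log axis, mean and SD of 3 libraries per group, PC12 as purple circles and SH-SY5Y as green squares. PC12 ribosomal RNA goes from 307.8 CPM in DMEM to 19040 CPM after H2O2 and messenger RNA from 37410 to 11700 CPM; SH-SY5Y messenger RNA differs 1.01-fold.

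The counts of called genes in PC12 depended on single libraries. Extract high called 1423 genes (744 up, 679 down), and 618 and 746 without H2O2 replicate 1 and 2, 723 and 694 without extract high replicate 1 and 2. Ergosterol high called 1337 (726 up, 611 down), and 680 and 623 without H2O2 replicate 1 and 2 and 550 without ergosterol high replicate 3. Mannitol low called 805 (414 up, 391 down), 126, 234 and 445 without H2O2 replicate 1, 2 and 3, and 1254 and 1863 without mannitol low replicate 2 and 3. Mannitol high called 479 (255 up, 224 down), 163, 138 and 302 without H2O2 replicate 1, 2 and 3, and 91 without mannitol high replicate 3. Extract low called 49 (31 up, 18 down), 7, 8 and 21 without H2O2 replicate 1, 2 and 3, and 12, 23 and 6 without extract low replicate 1, 2 and 3. Ergosterol low called 22 (7 up, 15 down), 8, 11 and 14 without H2O2 replicate 1, 2 and 3, and 8, 4 and 9 without ergosterol low replicate 1, 2 and 3. Mannitol low replicate 1 stood apart from the other libraries on the second principal component (39.47, the others lying between −5.98 and 2.99). Fitted on the 6 libraries of each comparison alone, with spread estimated from those groups, extract low gave 370 genes, ergosterol low 454, extract high 2256 and mannitol low 3.

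In SH-SY5Y, the 18 treated libraries differed from the H2O2 group in 9560 genes, 4899 higher and 4661 lower, 455 of them by more than 2-fold. GDF15 fell to 165.6 ± 28 CPM (−1.06 ± 0.114; SD, n = 18 and 3) and CDKN1A to 441.3 ± 56.2 CPM (−0.93 ± 0.0833), while GRIA2 rose to 26.68 ± 3.98 CPM (1.33 ± 0.125). PNISR, a splicing-related nuclear protein gene, rose from 119.7 ± 19.9 to 263.8 ± 29.1 CPM (1.14 ± 0.0964), the cyclophilin-related gene NKTR by 1.14 ± 0.103, and the centrosomal scaffold gene AKAP9 by 1.04 ± 0.107. Of 21 p53 targets 13 fell and 2 rose (median −0.232, camera adjusted p = 8.31e-05; adjusted p = 0.149 with an estimated correlation), with AEN at −0.49 ± 0.05 and TNFRSF10B at −0.38 ± 0.04. Ribosomal protein genes fell in 14 of 15 (15 adjusted over the list alone; median −0.322, adjusted p = 1.28e-09; adjusted p = 0.149 with an estimated correlation). Of 15 ATF4 targets 11 fell and 1 rose, including the serine synthesis gene PHGDH (−0.47), and of 16 DNA replication genes 13 fell and 2 rose, with MCM7 at −0.34 (adjusted p = 0.000417 and 0.000227; adjusted p = 0.149 with an estimated correlation for both). Except for the ribosomal list, these counts were the same adjusted over the list alone. Mitosis genes went both ways, 6 up and 6 down, TOP2A, a DNA topoisomerase, rising by 0.69 ± 0.06.

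The change in SH-SY5Y ran with GC content. Genes in the lowest 20% of GC had a median log2 fold change of 0.387 in treated cells against H2O2 and those in the highest 20% −0.293 (Spearman −0.617 across genes). The slope of log2 CPM on GC, per 10 points of GC, was 0.24 ± 0.0621 in the 3 H2O2 libraries (SD) and between −0.124 and 0.086 in the other 21, DMEM included. With the GC and length trends removed, 6998 genes were called, of which 4780 were among the 9560 and in the same direction and 465 in the opposite direction. In that fit 17 of 21 p53 targets fell and none rose, 11 of 15 ribosomal protein genes fell, 11 of 16 DNA replication genes fell and 10 of 15 ATF4 targets fell, the median of the ATF4 targets going from −0.385 to −0.199.

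**Figure D4:**
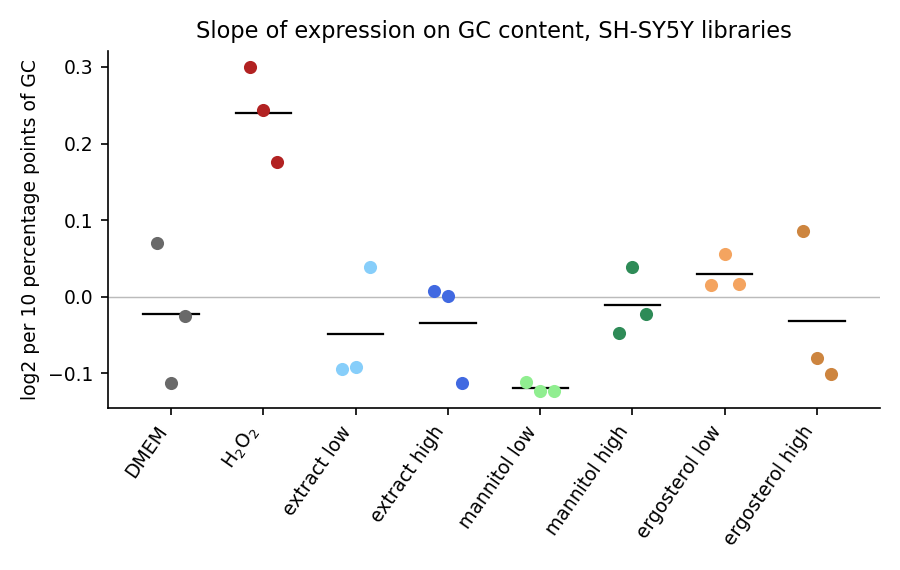
Slope of log2 CPM on GC content in each SH-SY5Y library, relative to the mean of all libraries and per 10 percentage points of GC, one dot per library and a bar at each group mean. The 3 H2O2 libraries lie between 0.176 and 0.3, above the other 21.

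Each SH-SY5Y treatment gave a change of similar size. GDF15 fell by 0.92 ± 0.162 with extract low, 0.79 with extract high, 1.13 with mannitol low, 1.17 with mannitol high, 1.04 with ergosterol low and 1.28 ± 0.164 with ergosterol high (n = 3 each). GRIA2 rose by between 1.08 with extract low and 1.56 with ergosterol high. CDKN1A fell by 0.72 ± 0.118 with extract high and 1.11 ± 0.119 with ergosterol high. Other genes among the steepest were the transcription factor gene SOX9 (−0.85, ergosterol low), CEBPB (−0.88, extract low), the cytokine receptor TNFRSF12A (−0.92, ergosterol high), the vessel growth factor ANGPT1 (1.32, mannitol low) and SLC44A5, a choline transporter-like protein gene (1.17, ergosterol high). Across the 6 groups, 12 to 14 of the 15 ribosomal protein genes, 11 to 13 of the 21 p53 targets, 7 to 11 of the 15 ATF4 targets and 10 to 12 of the 16 DNA replication genes fell (12 to 15, 12 to 14, 7 to 12 and 12 to 13 adjusted over the list alone). Up to 3 p53 targets, 2 ATF4 targets and 2 DNA replication genes rose (5, 2 and 2 adjusted over the list alone). The camera adjusted p was at most 0.0257 for these lists, and the lowest adjusted p = 0.0945 with an estimated correlation. Called genes numbered 7374 with extract low (3829 up, 3545 down), 7824 with extract high (4106 up, 3718 down), 9069 with mannitol low (4587 up, 4482 down), 7199 with mannitol high (3885 up, 3314 down), 6358 with ergosterol low (3552 up, 2806 down) and 7951 with ergosterol high (4232 up, 3719 down). With the GC and length trends removed, 10 to 11 ribosomal protein genes, 13 to 20 p53 targets, 4 to 10 ATF4 targets and 8 to 11 DNA replication genes fell. The ATF4 median went from −0.327 to −0.12 with extract low and from −0.309 to −0.118 with mannitol low. In that fit extract low gave 4069 and mannitol low 5610; the other groups stayed within 1.5 times their count.

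Whether treated cells had moved back toward the DMEM state was read from the genes that H2O2 changed. Among the 9594 such genes in SH-SY5Y, 7137 were called in the opposite direction in treated cells and 122 in the same direction, and the fold changes had a slope of −0.422 on those of H2O2. Both comparisons use the same H2O2 libraries. Draws of all libraries, with the treated groups unchanged from H2O2, gave a slope of −0.0596. Such draws hold no bias of the real H2O2 libraries, such as their GC slope, so they may understate what a shared control gives. With the GC and length trends removed the observed slope was −0.349. On a scale from 0 at DMEM to 1 at H2O2, the treated groups stood at 0.672 ± 0.0637 and 0.676 ± 0.0311 (extract low and high), 0.617 ± 0.0171 and 0.624 ± 0.0222 (mannitol) and 0.652 ± 0.0505 and 0.573 ± 0.0405 (ergosterol; SD, n = 3). In PC12, 755 of 9284 genes were called in the opposite direction and 166 in the same one, with a slope of −0.113 against −0.0339 simulated. PC12 positions were 0.951 ± 0.0397 and 0.847 ± 0.0251 (extract low and high), 0.949 ± 0.0433 and 0.897 ± 0.0733 (mannitol), and 0.948 ± 0.0124 and 0.847 ± 0.0836 (ergosterol). The genes and both ends of the scale came from the same DMEM and H2O2 libraries. No position was simulated, so how far under 1 an unchanged group would stand is not known. The GC and length trends were not removed from the positions. Tested against DMEM, 8740 to 9462 genes were called in the 6 PC12 groups and 2612 to 4566 in the SH-SY5Y groups. By the labels no DMEM group was collected at the later time of the treated groups. These counts and the positions therefore span that time as well. Fold changes of treatment pairs correlated across genes, with a median Pearson coefficient of 0.5859 over the 15 pairs in PC12 (simulated 0.5048) and 0.8023 in SH-SY5Y (simulated 0.5141). The covariances were 0.0981 against 0.0456 simulated and 0.1707 against 0.0349. Pairs shared a median of 38 called genes of the same direction in PC12 (2.155 expected of independent lists, 0 simulated) and 6270 in SH-SY5Y (1487 expected, 0 simulated). The 3 control libraries are too few to be split, so part of the excess may come from sharing them.

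**Figure D5:**
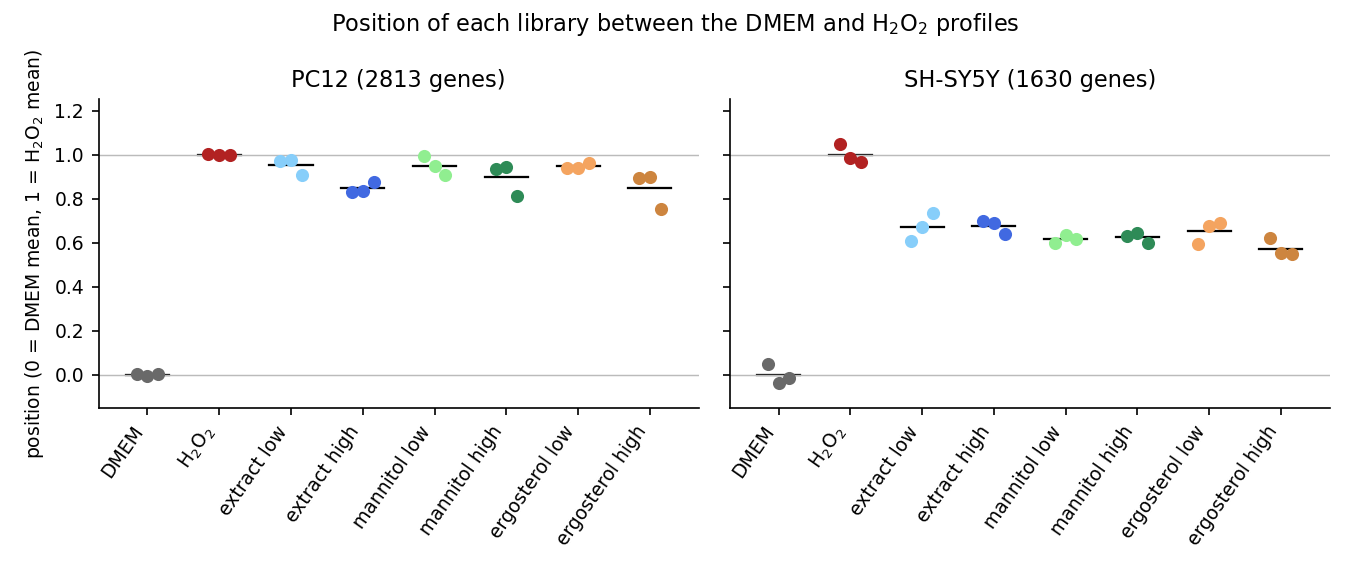
Position of each library on the axis from the DMEM mean (0) to the H2O2 mean (1), one dot per library and a bar at each group mean, computed over the genes that H2O2 changed by more than 2-fold. Treated group means lie between 0.847 and 0.951 in PC12 and between 0.573 and 0.676 in SH-SY5Y.

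The third question was whether dose mattered, which time does not confound. In PC12, the high dose of extract gave lower Serpinb2 than the low dose (2.16 ± 0.503 against 12.06 ± 2.67 CPM; −2.47 ± 0.333, n = 3 each), lower Klf2 (−1.55 ± 0.261) and lower Hsph1 (−1.47 ± 0.24), and higher Egr2 (0.39 ± 0.0884) and Tbx2, a T-box factor gene (0.40 ± 0.0931). Heat shock genes were lower in 7 of 12 (11 adjusted over the list alone; median −0.633, camera adjusted p = 1.06e-21), among them the HSP40 gene Dnajb1 (−1.25 ± 0.20). Cholesterol synthesis genes were lower in 3 of 20 (8 adjusted over the list alone; adjusted p = 5.74e-07), with Insig1 at −0.47 ± 0.10, and Slc5a3 was lower by −1.38 ± 0.17. Between the ergosterol doses Klf2 was lower at the high one, 7.256 ± 0.519 against 22.89 ± 1.24 CPM (−1.66 ± 0.258), Serpinb2 −1.54 ± 0.302 and heat shock genes lower in 5 of 12 (9 adjusted over the list alone; median −0.624, adjusted p = 3.71e-20), with Hspa8 at −0.45 ± 0.08. The replication fork gene Timeless was higher (0.37 ± 0.08). DNA replication genes reached the threshold only adjusted over the list alone, 8 higher with extract (adjusted p = 5.74e-07; adjusted p = 0.0866 with an estimated correlation) and 9 with ergosterol (adjusted p = 4.95e-08; adjusted p = 0.0526 with an estimated correlation). The extract doses differed in 72 genes (10 up, 62 down) and the ergosterol doses in 36 (2 up, 34 down). The 72 became 21, 15 and 141 without extract low replicate 1, 2 and 3 and 14 and 15 without extract high replicate 1 and 2. The 36 became 2, 2 and 1 without ergosterol low replicate 1, 2 and 3 and 4, 15 and 1 without ergosterol high replicate 1, 2 and 3. EdgeR called 0 genes between the mannitol doses (2193 at an unadjusted p under 0.05; DESeq2 called 4), but 1103 without mannitol low replicate 3 and 1 without mannitol high replicate 2.

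In SH-SY5Y, the mannitol doses were compared in the same way. IGFBP3, which binds insulin-like growth factors, was lower at the high dose (17.45 ± 0.187 against 26.06 ± 1.58 CPM; −0.58 ± 0.113, n = 3 each), as were SCG2, a secretory granule protein gene (−0.47 ± 0.0798), and SLC7A11, the cystine importer gene (−1.20 ± 0.20; adjusted p = 0.00665). DLL3, a Notch ligand gene, was higher (0.52 ± 0.113) and MAPT, which encodes tau, was higher (0.39 ± 0.08). The 29 genes (15 up, 14 down) became 17, 0 and 8 without mannitol low replicate 1, 2 and 3 and 14, 4 and 19 without mannitol high replicate 1, 2 and 3, and fold changes rose with GC content (Spearman 0.44). With the GC and length trends removed the mannitol doses gave 72 genes and the extract doses 32. The extract doses gave 0 called genes by edgeR (1230 at an unadjusted p under 0.05; DESeq2 12), though ER chaperones were lower in 8 of 15 adjusted over the list alone (0 over all genes; median −0.168, camera adjusted p = 4.99e-13), with HSPA5, the main ER chaperone gene, at −0.28 ± 0.05 and MANF at −0.28. Leaving out extract low replicate 1 gave 2 genes and extract high replicate 2 gave 1. In fits of the extract libraries alone, another split called up to 1287 genes, against 2 for the real doses. The difference in ER chaperones can therefore not be laid to the dose. The ergosterol doses gave 0 by edgeR (951 at an unadjusted p under 0.05; DESeq2 called 0 as well).

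The last question was whether the compounds differed from each other, each against the other compounds pooled. In PC12, extract gave lower Postn (7.249 ± 2.27 against 16.97 ± 2.07 CPM; −1.26 ± 0.0897, n = 6 and 12; adjusted p = 7.89e-10), lower Pmepa1, a TGF-beta-induced gene (106.2 ± 7.54 against 155.9 ± 8.45 CPM; −0.55 ± 0.0361), and lower basement membrane collagen Col4a1 (−0.52 ± 0.0659) and Serpinf1 (−0.48 ± 0.0387). It gave higher Plpp3, a lipid phosphatase gene (0.38 ± 0.0638), Id2 (0.34 ± 0.0548), Nampt, an enzyme of NAD synthesis (0.25 ± 0.0377), and the granule gene Scg2 (0.37 ± 0.05). NRF2 targets were higher in 2 of 16 (3 adjusted over the list alone; camera adjusted p = 5.75e-05; adjusted p = 0.0943 with an estimated correlation), the pentose phosphate genes Tkt (0.18 ± 0.04) and Taldo1 (0.17 ± 0.04). Mannitol gave higher Lif, a cytokine gene (481.7 ± 25.3 against 389.7 ± 34.3 CPM; 0.31 ± 0.045, adjusted p = 0.00108), and ergosterol lower Nfkbia (−0.28 ± 0.05). The counts were 146 for extract (87 up, 59 down), 7 for mannitol (7 up) and 12 for ergosterol (8 up, 4 down). For extract, 93, 66 and 86 genes were called without extract low replicate 1, 2 and 3, 74 and 61 without extract high replicate 1 and 2, and 411 without mannitol low replicate 1. For mannitol the count was 15 and 27 without mannitol low replicate 1 and 3. For ergosterol, 14 of the 18 libraries moved the count, to between 3 (without ergosterol low replicate 3) and 31 (without mannitol low replicate 1). It was 7, 6 and 7 without extract low replicate 1, 2 and 3, 6 and 6 without extract high replicate 1 and 2, and 6, 7 and 19 without mannitol high replicate 1, 2 and 3. It was 5 and 6 without ergosterol low replicate 1 and 2, and 3 and 5 without ergosterol high replicate 1 and 2.

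In SH-SY5Y extract gave lower ABCA12, a lipid transporter gene (76.1 ± 3.86 against 89.16 ± 3.6 CPM; −0.23 ± 0.04, n = 6 and 12), and higher EDA2R, a p53-regulated receptor gene (0.21 ± 0.04). The p53 targets were higher in 10 of 21 adjusted over the list alone (1 over all genes; camera adjusted p = 1.64e-11; adjusted p = 0.072 with an estimated correlation). Ergosterol gave higher PPFIA4, a presynaptic scaffold gene (0.35 ± 0.0713), and lower RORB, a nuclear receptor gene (−0.29 ± 0.0485), and SSH2, a cofilin phosphatase gene (−0.18 ± 0.0368). The counts were 23 for extract (18 up, 5 down), 1 for mannitol (higher) and 37 for ergosterol (14 up, 23 down). They rose to 172, 31 and 281 with the GC and length trends removed and to 41, 29 and 271 without the filter on low counts. DESeq2 gave 11 for mannitol and 129 for ergosterol. Other splits of the treated SH-SY5Y libraries called up to 2183, 574 and 954 genes in place of extract, mannitol and ergosterol, so these differences cannot be laid to the compounds. For extract, 13 of the 18 libraries moved the count: 15, 10 and 11 without extract low replicate 1, 2 and 3, and 11, 6 and 9 without extract high replicate 1, 2 and 3. Further values were 13, 15 and 15 without mannitol low replicate 1, 2 and 3, 13 without mannitol high replicate 1, and 11, 13 and 9 without ergosterol low replicate 1, 2 and 3. For ergosterol the count was 56 without extract low replicate 3, 16 and 20 without ergosterol low replicate 1 and 2, and 23 without ergosterol high replicate 1. The single gene of mannitol was lost without extract low replicate 1 or 3, extract high replicate 1, mannitol low replicate 1 or 2 and ergosterol high replicate 2. The mannitol count was 5 without extract high replicate 3, 4 without ergosterol high replicate 1, 3 without mannitol high replicate 3 or ergosterol low replicate 1, and 2 without extract high replicate 2, mannitol high replicate 1, ergosterol low replicate 3 or ergosterol high replicate 3.

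The effects of treatment were compared between the lines by interactions, described here for heat shock and DNA replication genes with extract high and ergosterol high. Other lists stood before them elsewhere. With extract low, p53 targets and ER chaperones (camera adjusted p = 0.000724 each) came before DNA replication genes (camera adjusted p = 0.00163). With extract high, 10 of 12 heat shock genes had a less negative effect in SH-SY5Y (adjusted p = 6.06e-13; median −1.08 in PC12), among them HSPH1 (2.64 ± 0.244), whose change in SH-SY5Y turned negative (−0.099) once GC and length trends were removed. Within SH-SY5Y these genes went both ways, so no direction is given for the list: the median was 0.202 over the 12 genes of the interaction and −0.227 over the 13 tested in that line alone (5 up and 7 down, the same adjusted over the list alone; −0.111 with the trends removed). With ergosterol high, 12 of 15 DNA replication genes rose in PC12 relative to SH-SY5Y (medians 0.308 and −0.225, adjusted p = 8.63e-13). In addition 9 heat shock genes had a less negative effect in SH-SY5Y (adjusted p = 1.8e-09; adjusted p = 0.091 with an estimated correlation). Adjusted over the list alone the interaction counts of 10, 12 and 9 were 10, 12 and 10. Genes with a different effect numbered 3534 with extract high, 3145 with ergosterol high, 4551 and 2463 with mannitol low and high, 2628 with extract low and 1955 with ergosterol low. None of these interactions was fitted with the GC and length trends removed.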

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

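The tests of all 3 patterns weighed here were chosen after the pattern was seen, and so was the rule that interaction splits keeping the real groups of 1 line are counted apart; the other counts over splits of the samples were fixed before.

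Between the lines, the interaction test called 6416 genes for the H2O2 effect, and the difference of responses is what put them here. The same test called 2628 genes for extract low, 3534 for extract high, 4551 for mannitol low, 2463 for mannitol high, 1955 for ergosterol low and 3145 for ergosterol high, each against H2O2. Among splits that mix the groups of both lines, counted with the real grouping, 1 of 60 gave as many genes for H2O2 (6686 in the fit of these libraries; highest other 0). The share was 1 of 30 each for extract low (3172; 1), extract high (3869; 0), mannitol low (3432; 0), mannitol high (2891; 0), ergosterol low (2953; 1) and ergosterol high (2940; 0). Each is the smallest share that so many splits can give, with no allowance for the number of interactions. These splits deal single libraries over the groups and so mix real groups, which can widen the spread within groups. Low counts in the other splits are therefore likely from the way they are made, and chance is not excluded by them. The splits do not test a trend of the libraries with GC content or length. No interaction was fitted with those trends removed, and each uses the SH-SY5Y H2O2 libraries, whose GC slope stood apart from the other 21. Splits that keep the real groups of 1 line hold the effect of that line and were counted apart. Their highest values were 4601 for H2O2, 4068 and 2465 for extract low and high, 2987 and 3143 for mannitol and 3525 and 2701 for ergosterol. As many genes as the real grouping came from 4 of 11 of them for extract low, 1 of 8 for mannitol high and 3 of 9 for ergosterol low, so the effect of 1 line is enough for such a count there. The lines were also sequenced under separate batch labels, so batch and line cannot be told apart.

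The libraries labelled PC12 showed almost none of the chromaffin program. Of 16 catecholamine and secretory granule genes 10 were under 1 CPM in every library, the median was already 0.0375 CPM in DMEM, and so loss through the peroxide is argued against. A second list of 16 chromaffin genes, written down before it was looked up, had 6.25% of its members at 10 CPM or more in DMEM (Cplx2 alone, 35.8 CPM), which is consistent with cells of another type than chromaffin tumour cells. A second Schwann list had 57.1% of 14 members at 10 CPM or more, led by Itga6 (1310 CPM), Gpm6b (1010 CPM), Itgb8 (440 CPM) and Sox2 (346 CPM), genes that other tissues also express. The members under 10 CPM were almost absent in DMEM: Mal and Gjb1 (0 CPM each), Mbp (0.169 CPM), Nrcam (0.251 CPM), Matn2 (0.374 CPM) and Col28a1 (0.948 CPM). The list thus does not settle which type of cell these are. A subline of PC12 that lost this program stays open, since no reference profile of such a line was at hand.

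Mitochondrial RNA in PC12 went in opposite directions by kind: rRNA was 61.9-fold higher after H2O2 and messenger RNA fell to 0.313 of its DMEM level, a pattern absent in SH-SY5Y (1.41-fold and 1.01-fold). In rRNA level the PC12 DMEM libraries stood apart, at 307.8 CPM. The exposed PC12 groups had means of 10160 to 19040 CPM, and SH-SY5Y had 9854 CPM in DMEM and 13940 CPM after H2O2. The levels alone do not tell a rise through peroxide from unusually low rRNA in the PC12 DMEM libraries. Weaker poly(A) selection or rRNA removal is argued against only as far as the annotated nuclear rRNA genes can show it. Their sum differed 1.11-fold, from 1117 ± 72.2 CPM in DMEM to 1239 ± 46.4 CPM after H2O2. Which kinds of nuclear rRNA these genes cover was not checked. Weaker removal of mitochondrial rRNA alone is argued against for the messenger RNA, whose lowest DMEM library stood 2.56 times above the highest exposed one with rRNA out of the totals; for the rRNA rise (61.9-fold) it stays open, since removal may have differed between the DMEM and exposed libraries, although such removal alone would not tie the rRNA to nuclear genes. Across the 18 treated libraries, log2 mitochondrial rRNA followed the position between DMEM and H2O2 over 2797 nuclear genes (Pearson 0.937, Spearman 0.874, each with permutation p = 1e-05, the smallest that 100000 resamples give; Pearson 0.884 without the 2 farthest libraries and 0.911 with group means removed, p = 0.00436). For the rRNA, a mitochondrial response that fades with the rest of the peroxide profile is a candidate explanation, as a hypothesis. For the messenger RNA such fading is argued against. All 6 treated means lay below that of H2O2 (7208 to 11210 against 11700 CPM), and in 4 of the 6 groups every library lay below the lowest H2O2 library. The highest library was at 14400 CPM in ergosterol high and 11510 CPM in mannitol high, against 11200 to 12250 CPM in the H2O2 libraries. The lowest mean, of mannitol low, includes a library at 2502 CPM.

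All 6 treated SH-SY5Y groups moved away from the H2O2 libraries in 1 common direction, partly along GC content. The GC and length trends that were removed are argued against as the whole cause, since 6998 genes were called without them. Only 4780 of these, 50% of the 9560 shifted genes, were shifted genes called in the same direction. Another 465 were called in the opposite direction, and the rest of the 6998 had no call before the removal. The median absolute log2 fold change of the shifted genes went from 0.365 to 0.166. A bias that the splines do not take out was not tested, so a bias of the H2O2 libraries stays open. For the shifted genes whose call ended, bias and biology cannot be told apart because the trend runs with the groups. Of the shifted genes 0.471% (45 of 9560) were called between compounds or doses, but 3.84% (269 of 6998) with the trends removed, so an action specific to a compound stays open for part of the shift. Time after peroxide cannot be told apart from any action shared by the compounds, because 0 libraries had peroxide and the further 24 h without a compound.

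Other splits of the samples were counted for each comparison, in fits of only the libraries compared. With 18 treated against 3 H2O2 libraries, 1 of 40 splits gave as many genes in PC12 (925, highest other 3) and in SH-SY5Y (9604, highest other 6487). The share is under 0.05 in each line. These splits deal single libraries over the groups and so mix real groups, which can widen the spread within groups. For the PC12 compounds against the others the share was also 1 of 40 each: extract (65, highest other 3), mannitol (5, highest other 0) and ergosterol (4, highest other 1). It is the smallest share that 40 splits can give, with no allowance for 3 compounds. For extract the real count stood far above the others. The counts of mannitol and ergosterol are too small for these splits to exclude chance. In SH-SY5Y it cannot be excluded for extract (2 of 40; 23 against 2183), mannitol (3 of 40; 7 against 574) or ergosterol (2 of 40; 78 against 954); splits that call many times the real count point to a structure of these samples other than the compounds.

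Groups of 3 against 3 make 10 splits, too few for a share under 0.05. In PC12 the real value and the highest other were 9883 and 0 for H2O2, 370 and 3 for extract low, 2256 and 0 for extract high, 3 and 0 for mannitol low, 845 and 0 for mannitol high, 454 and 1 for ergosterol low, 1678 and 0 for ergosterol high, 343 and 9 for the extract doses, 0 and 0 for the mannitol doses and 98 and 1 for the ergosterol doses. In SH-SY5Y they were 8903 and 0 for H2O2, 7092 and 0, 7744 and 0 for extract low and high, 9370 and 1, 6855 and 0 for mannitol low and high, 6848 and 1, 7044 and 1 for ergosterol low and high, 2 and 1287 for the extract doses, 808 and 1 for the mannitol doses and 0 and 844 for the ergosterol doses. The extract and ergosterol doses of SH-SY5Y thus have splits with many times the real count, which points to a structure of those libraries. Against DMEM the values in PC12 were 9860, 9390, 7590, 9469, 10071 and 9122 for extract, mannitol and ergosterol, low before high, with 0 as the highest other in each. In SH-SY5Y they were 3448, 3411, 4901, 2463, 3312 and 1568, with highest others of 1, 1, 0, 1, 1 and 192. As many genes as the real split were given by 1 of the 10 splits everywhere here, except 2 of 10 for the SH-SY5Y extract doses and all 10 for the PC12 mannitol doses and the SH-SY5Y ergosterol doses.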

How the results depend on the processing

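The tests with gene length, with gene length and GC content, and without both libraries that stand apart (PC12 mannitol low replicate 1 and ergosterol high replicate 3) were chosen after the results were seen; the other settings were fixed before. Of 17731 values of named genes under the settings fixed before, 16522 kept their direction and side of the threshold, 1209 kept the direction but lost the call, and 0 turned. Of 2708 values under the later settings, 2368 kept both, 281 lost the call and 59 turned. Of 1511 list tests, 1141 had the same outcome as camera, called or not called, 268 lost a call of camera and 102 gained one. The 1141 include lists that neither test called, so they are not a count of camera calls that held. Of 427 counts of called genes under the earlier settings 282 stayed within 1.5 times the reported count, and of 56 under the later settings 35 did. The H2O2 counts of both lines and the interaction count stayed within 1.5 times under every setting run on them. The counts of treated PC12 groups against H2O2 and the counts between doses or compounds moved most, and the cause was not tested, except that a fit of only the groups compared estimates the spread from fewer libraries. Replicate numbers do not pair the libraries, and the block moved no other count by more than 1.5 times: deviations of libraries with the same replicate number correlated at a mean of 0.011 (−0.314 to 0.331 over 84 pairs of groups) in PC12 and −0.00373 (−0.346 to 0.43) in SH-SY5Y, and 11 and 7 of 24 libraries were closest to their own number. In the simulations the smallest fold change tried was recovered for 34% of genes in PC12, and recovery was not split by depth or by count.

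With the DESeq2 Wald test, PC12 gave 191 for extract low (49 before), 1317 for mannitol low (805 before), 761 for mannitol high (479 before), 95 for ergosterol low (22 before), 206 for extract doses (72 before), 4 for mannitol doses (0 before), 92 for ergosterol doses (36 before), 295 for extract against other compounds (146 before), 30 for mannitol against other compounds (7 before), 27 for ergosterol against other compounds (12 before), and SH-SY5Y gave 12 for extract doses (0 before), 79 for mannitol doses (29 before), 11 for mannitol against other compounds (1 before), 129 for ergosterol against other compounds (37 before). Without the filter on low counts, PC12 gave 146 for extract doses (72 before), 3 for mannitol doses (0 before), 14 for mannitol against other compounds (7 before), 19 for ergosterol against other compounds (12 before), and SH-SY5Y gave 14 for extract doses (0 before), 254 for mannitol doses (29 before), 41 for extract against other compounds (23 before), 29 for mannitol against other compounds (1 before), 271 for ergosterol against other compounds (37 before). Fitting only the groups compared, PC12 gave 370 for extract low (49 before), 2256 for extract high (1423 before), 3 for mannitol low (805 before), 845 for mannitol high (479 before), 454 for ergosterol low (22 before), 343 for extract doses (72 before), 98 for ergosterol doses (36 before), 65 for extract against other compounds (146 before), 4 for ergosterol against other compounds (12 before), and SH-SY5Y gave 2 for extract doses (0 before), 808 for mannitol doses (29 before), 7 for mannitol against other compounds (1 before), 78 for ergosterol against other compounds (37 before). With gene length adjusted, PC12 gave 31 for extract low (49 before), and SH-SY5Y gave 3 for extract doses (0 before), 5 for mannitol against other compounds (1 before). Without both libraries that stand apart, PC12 gave 511 for extract low (49 before), 2941 for extract high (1423 before), 1578 for mannitol high (479 before), 169 for ergosterol low (22 before), 2384 for all treated groups (1147 before), 627 for extract doses (72 before), 12 for ergosterol doses (36 before), 563 for extract against other compounds (146 before), 21 for mannitol against other compounds (7 before), 64 for ergosterol against other compounds (12 before). With median-ratio size factors, SH-SY5Y gave 2 for extract doses (0 before), 3 for mannitol against other compounds (1 before). With the replicate number as a block, SH-SY5Y gave 4 for mannitol against other compounds (1 before). With gene length and GC content adjusted, SH-SY5Y gave 4069 for extract low (7374 before), 5610 for mannitol low (9069 before), 32 for extract doses (0 before), 72 for mannitol doses (29 before), 1 for ergosterol doses (0 before), 172 for extract against other compounds (23 before), 31 for mannitol against other compounds (1 before), 281 for ergosterol against other compounds (37 before).

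The genes that turned did so in SH-SY5Y with length and GC content adjusted, which by construction removes the part of a change that follows GC content and length; their values in that fit, by comparison against H2O2 (H2O2 itself against DMEM), are these. SEL1L was at 0.0020 (H2O2), −0.011 (extract high), −0.097 (mannitol low), −0.059 (mannitol high), −0.059 (ergosterol low), −0.026 (ergosterol high), −0.039 (all treated groups). SNAP25 was at 0.037 (H2O2), −0.17 (extract low), −0.11 (extract high), −0.19 (mannitol low), −0.10 (mannitol high), −0.071 (ergosterol low), −0.17 (ergosterol high), −0.14 (all treated groups). NFKBIA was at −0.064 (H2O2). IREB2 was at 0.076 (H2O2), −0.020 (mannitol low), −0.035 (mannitol high), −0.035 (ergosterol low), −0.068 (ergosterol high), −0.019 (all treated groups). MSH6 was at 0.015 (H2O2), −0.085 (extract low), −0.099 (mannitol low), −0.050 (mannitol high), −0.080 (all treated groups). DNAJB11 was at −0.20 (extract low), −0.17 (mannitol high). HSPH1 was at −0.035 (extract low), −0.099 (extract high), −0.0043 (mannitol low), −0.10 (ergosterol high), −0.054 (all treated groups). SLC38A2 was at −0.013 (extract low), −0.0010 (extract high), −0.036 (ergosterol low), −0.031 (ergosterol high), −0.029 (all treated groups). HSPA4L was at −0.095 (extract low), −0.11 (extract high), −0.12 (mannitol low), −0.10 (mannitol high), −0.12 (all treated groups). SLC5A3 was at −0.038 (extract low), −0.024 (mannitol high), −0.011 (ergosterol low), −0.040 (ergosterol high), −0.013 (all treated groups). XIAP was at −0.11 (extract low). CHGA was at 0.12 (extract low). LAMP2 was at −0.16 (extract low). STARD4 was at −0.042 (mannitol low), −0.041 (ergosterol high). NFKB2 was at 0.019 (mannitol low). FGF2 was at −0.048 (mannitol low), −0.051 (ergosterol low). HMGCS1 was at −0.0018 (mannitol high). NFAT5 was at −0.061 (mannitol high).

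Leaving out 1 library at a time gave these ranges. In PC12 they were 8652 to 8719 for H2O2, 6 to 23 for extract low, 618 to 1236 for extract high, 126 to 1863 for mannitol low, 91 to 353 for mannitol high, 4 to 14 for ergosterol low, 550 to 1133 for ergosterol high, 347 to 2255 for all treated groups, 14 to 141 for extract doses, 61 to 411 for extract against other compounds, 6 to 27 for mannitol against other compounds, 3 to 31 for ergosterol against other compounds, 0 to 1103 for mannitol doses, 1 to 15 for ergosterol doses. In SH-SY5Y they were 8180 to 9469 for H2O2, 5599 to 7603 for extract low, 6251 to 7532 for extract high, 7573 to 8776 for mannitol low, 5309 to 7069 for mannitol high, 4493 to 6252 for ergosterol low, 6222 to 8243 for ergosterol high, 7447 to 9845 for all treated groups, 0 to 2 for extract doses, 6 to 19 for extract against other compounds, 0 to 5 for mannitol against other compounds, 16 to 56 for ergosterol against other compounds, 0 to 19 for mannitol doses, 0 to 0 for ergosterol doses. The interaction of the H2O2 effect gave 6014 to 6305.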

Other observations

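In PC12, single members of lists not described above moved far after H2O2. Stmn4, a stathmin of neurites, rose by 6.89 ± 0.464, Adm, which encodes adrenomedullin, by 4.03 ± 0.263 and the trophic factor gene Gdnf by 1.84 ± 0.16 (SE, n = 3 and 3). The neurotrophin receptor gene Ntrk2 fell by 1.86 ± 0.135. Of 9 LXR targets 6 fell and 2 rose (camera adjusted p = 0.0462; adjusted p = 0.239 with an estimated correlation). Among them the desaturase gene Scd fell by 1.91 ± 0.105 and the cholesterol exporter gene Abca1 by 1.33 ± 0.14, while Apoe rose by 1.58 ± 0.2. Antioxidant enzymes rose in 10 and fell in 2 of 16 (adjusted p = 0.0195; adjusted p = 0.124 with an estimated correlation). DNA repair genes fell in 9 and rose in 2 of 15 (adjusted p = 0.00441; adjusted p = 0.127 with an estimated correlation). No camera call was made for ATF4 targets (7 up and 4 down of 15, adjusted p = 0.115), ER chaperones (10 up and 3 down of 15, adjusted p = 0.101), osmotic response genes (3 up and 5 down of 10, adjusted p = 0.661) or autophagy genes (8 up and 4 down of 16, adjusted p = 0.115). None was made for nuclear respiratory chain genes (7 up of 15, adjusted p = 0.208), glycolysis genes (6 up and 6 down of 15, adjusted p = 0.79) or growth factor genes (5 up and 3 down of 12, adjusted p = 0.721). The same held for neurite genes (3 up and 3 down of 10, adjusted p = 0.79), interferon genes (3 up and 3 down of 12, adjusted p = 0.79) and the 7 measured catecholamine genes (4 up and 1 down, adjusted p = 0.229). Adjusted over the list alone, the counts were 10 and 3 for antioxidant enzymes, 10 and 4 for ER chaperones, 4 and 5 for osmotic genes, 6 and 0 for respiratory chain genes, 7 and 6 for glycolysis genes, and otherwise as given.

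In SH-SY5Y, nuclear respiratory chain genes rose in 10 of 16 after H2O2 (adjusted p = 0.0032; adjusted p = 0.208 with an estimated correlation). Autophagy genes rose in 9 of 16 (10 adjusted over the list alone; adjusted p = 0.0032; adjusted p = 0.0755 with an estimated correlation), including the autophagy receptor gene SQSTM1 (1.13 ± 0.111). Apoptosis genes rose in 7 and fell in 3 of 19 (adjusted p = 0.00566; adjusted p = 0.0687 with an estimated correlation). Antioxidant enzymes rose in 12 and fell in 4 of 17 (13 and 4 adjusted over the list alone; adjusted p = 0.000863; adjusted p = 0.0844 with an estimated correlation), GPX1 by 1.03 ± 0.0692. DNA replication genes rose in 10 and fell in 1 of 16 (11 and 1 adjusted over the list alone; adjusted p = 0.00305; adjusted p = 0.0844 with an estimated correlation). In treated cells against H2O2, antioxidant enzymes fell in 12 and rose in 3 of 17 (adjusted p = 0.00192; adjusted p = 0.149 with an estimated correlation). Glycolysis genes fell in 10 and rose in 1 of 16 (adjusted p = 0.0022; adjusted p = 0.149 with an estimated correlation), with ENO1 at −0.42 ± 0.0393. Respiratory chain genes fell in 10 and rose in 1 of 16 (adjusted p = 0.00796; adjusted p = 0.257 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. With the GC and length trends removed, 7 antioxidant enzymes fell and 1 rose, and their median went from −0.248 to −0.103. After H2O2 the same adjustment took the median of the antioxidant enzymes from 0.354 to 0.201 (8 up, 1 down) and that of the DNA replication genes from 0.244 to 0.101 (7 up, 3 down). In treated cells against H2O2, MAP2 rose by 0.65 ± 0.0521. After H2O2, camera made no call for ATF4 targets (adjusted p = 0.973), ER chaperones (0.17), LXR targets (0.862), osmotic response genes (0.958), catecholamine genes (0.402) or neurite genes (0.13). It made none for the 5 measured NF-kB genes (0.162), interferon genes (0.402), the mitochondrially encoded genes (0.958), glycolysis genes (0.466) or iron handling genes (0.162). Growth factor genes (0.357), DNA repair genes (0.532) and mesenchymal markers (0.143) also had no call. The Schwann and glial list had 4 measured members and was not tested.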
